A study of Solanum lycopersicum with 12 samples.

How the data were processed

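Messenger RNA was measured by sequencing of total RNA from tomato roots in 12 libraries, per the labels: WT and slstop1 plants, 20 days old, at 0 and 60 µM Al and pH 4.7, with 3 biological replicates per group. Groups and replicate numbers were taken from the sample titles. The authors deposited a single table with a value for each of 35768 gene models in each library. The deposited values are taken as FPKM: the table does not name its unit, its values have decimals, and its columns sum to between 696287 and 719916, which rules out raw counts and values scaled to a fixed total. The submitters' processing notes name TopHat2, HISAT2, StringTie and Cufflinks, without versions or the step each was used for. The genome build and annotation release are not given in the sources used here. FPKM divides fragments by transcript length and by library total, so a rise of abundant transcripts lowers every other value.

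The table was used with all its columns. Of its gene models 10712 were 0 in every library. A value of exactly 0 can be a failed estimate rather than an absent transcript: 328 genes had a 0 and a value of 10 FPKM or more in replicates of the same group. Of these, 47 were called for Al in WT, 44 for Al in slstop1, 1 between genotypes with Al, and none without Al or for the interaction. Where a named gene had a group with such zeros, the values of its libraries are given. Among gene models above 0, 1501 had values identical to those of another, mostly at low values, and 6 of them were tested. No library duplicated another: at least 95.5% of the tested genes differed between any pair.

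Absolute depth is unknown, so no counting interval is given. Relative depth was estimated from the ratios of low values (0.3 to 4 FPKM) between libraries, which pile up at the ratio of what 1 fragment is worth. Of 66 pairs of libraries, 59 lay within 0.03 (log2) of a single set of depths, which spanned a factor of 1.45. On simulated libraries of known depth the largest error was 0.011 (log2). Whole reads were not recovered, since transcript lengths were not used here.

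Values were transformed as log2(FPKM + 1), which understates the change of low genes. Genes with at least 1 FPKM in at least 3 of the 12 libraries were kept (15903). A group-means model over all 12 libraries was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with a trend), with 8 residual degrees of freedom. The comparisons were Al against no Al in each genotype, slstop1 against WT at each dose, and the interaction, which is the Al response in slstop1 minus that in WT. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no fold minimum. Errors of log2 changes are limma's standard errors. Library measures were compared with exact permutation tests, for which 0.1 is the smallest p. Figures were drawn with matplotlib 3.10.9, and depth was computed with numpy 2.4.6 in Python 3.11.15.

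The procedure was tested on simulated data, 15209 genes of which 200 were changed in WT with Al. The 200 were drawn from genes with higher mean values, and errors were independent between genes. The shares below therefore do not cover genes near 1 FPKM, and far fewer genes were changed than were called for Al in the real data. For the Al response in WT it called 57% of changes of 1 and 92% of changes of 2 on the log2 scale, with 9 unchanged genes called. For slstop1 against WT with Al it called 59% and 90%, with 8 unchanged genes called, and for the interaction 24% and 74%, also with 8. In the Al response of slstop1, where nothing was changed, it called 0 genes.

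The tests, the alternatives and the rule for named genes were fixed before the data were examined. Under that rule, a named gene passed the test, had groups that did not overlap (not required for the interaction; chance gives this to 10% of unchanged genes with 3 against 3), reached a mean of 5 FPKM in a compared group, and had the largest rise or fall on the log2 scale. A clause that asked for an informative description, and a larger number of named genes, were dropped once the table proved to hold no descriptions. The 2 largest in each direction are named instead. The reference gene table at hand (assembly SLM_r2.1) matched 0 of the identifiers. For that reason 52 gene lists fixed beforehand, which were to be matched by description and tested with camera, were not analysed here. Of 5 identifiers recorded beforehand, SlSTOP1 and FER were tested. SlIRT1 (Solyc02g069200.3) and SlFRO1 (Solyc01g094910.3) stayed under the filter, and SlALMT9 was not analysed here.

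The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalisation, eBayes without trend and with robust fitting, a fit of only the 6 libraries compared, the replicate number as a block, a log2 change of at least 1, and leaving out each library. Leaving the 100 most abundant genes of any library out of the total was added after seeing the data.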

Results

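The series profiled mRNA in roots of tomato (Solanum lycopersicum) by RNA sequencing. Roots came from 20-day-old plants of the wild type (WT) and of a mutant, slstop1, disrupted in the tomato homologue of STOP1. STOP1 is a zinc finger transcription factor that controls tolerance of acid soil and of aluminium (Al) ions in Arabidopsis. Plants of both genotypes were exposed to a solution at pH 4.7 with either 0 or 60 µM Al, which made 4 groups of 3 biological replicates, 12 libraries in all. Expression was given as FPKM, a fragment count divided by transcript length and by library total, for 35768 gene models. Of these, 15903 reached 1 FPKM in at least 3 libraries and were tested. The total number of reads per library is unknown, because the values are already divided by it. From the spacing of low FPKM values the deepest library was 1.45 times as deep as the shallowest.

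The gene models carry Solyc identifiers, which the deposited table does not pair with names. The identifiers of SlSTOP1 and of FER, a basic helix-loop-helix regulator of iron uptake, were recorded from published nomenclature before the data were examined. Other genes are given by identifier alone, at most 2 in each direction per comparison. Chromosome numbers are those contained in the identifiers.

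The targeted gene was lower in the mutant at both Al doses. SlSTOP1 (Solyc11g017140.2, chromosome 11) stood at 69.3 ± 12 FPKM (SD, n = 3) in WT without Al and at 36.0 ± 3.34 FPKM in slstop1 without Al. With Al it stood at 85.1 ± 3.93 FPKM in WT and 28.9 ± 1.20 FPKM in slstop1. Every slstop1 library lay below every WT library, between 27.6 and 39.8 FPKM against 56.0 to 88.6 FPKM. The log2 difference between genotypes was -0.91 ± 0.138 (SE; limma adjusted p = 0.0319) without Al and -1.52 ± 0.138 (adjusted p = 0.000172) with Al. Its change with Al was 0.31 in WT (adjusted p = 0.0753) and -0.30 in slstop1 (adjusted p = 0.0719), and neither passed the test. The rise in WT passed with median-of-ratios scaling (0.56, adjusted p = 0.00133; range over alternatives 0.00133 to 0.213), under which the change in slstop1 was 0.16; that in slstop1 passed with only its 6 libraries (adjusted p = 0.0243; range 0.0155 to 0.516). Fitted on the 6 libraries without Al alone, the same difference of -0.91 had an adjusted p of 0.442; over all alternatives that p ranged from 0.00389 to 0.442. A disrupted gene can keep part of its transcript, so the level alone does not show the nature of the mutation.

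**Figure D1:**
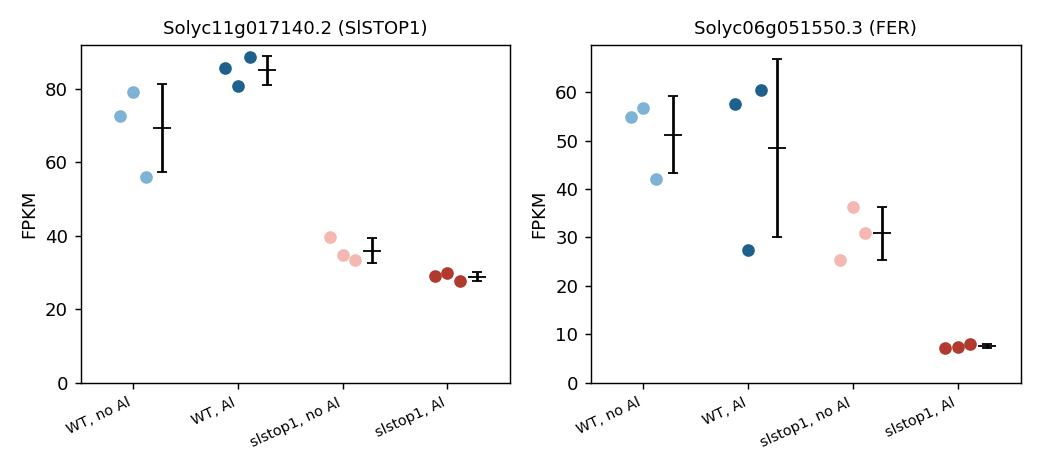
FPKM of SlSTOP1 (left) and FER (right) in each of the 12 libraries; points are libraries, and the bar beside them is the mean with its SD (n = 3). SlSTOP1 was at most 39.8 FPKM in the slstop1 libraries and at least 56.0 FPKM in the WT libraries, and FER was at most 7.97 FPKM in slstop1 with Al.

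Al exposure came with fewer genes at 1 FPKM or more and with a larger share for the most abundant ones. Both shifts were larger in slstop1. They are not independent, since a larger share of abundant genes lowers all other values and can take genes under 1 FPKM. Genes were not counted after scaling, so the drop need not mean that genes were switched off. WT libraries had 14471 ± 439 genes at 1 FPKM or more without Al and 13361 ± 181 with Al (SD, n = 3). In slstop1 the numbers were 14533 ± 32 and 12424 ± 171. The 10 most abundant genes of a library held 5.96 ± 0.786% of the summed FPKM in WT without Al and 7.51 ± 0.666% with Al, against 5.86 ± 0.382% and 11.2 ± 0.473% in slstop1. With Al, the genotypes did not overlap in either measure (exact permutation test, two-sided, p = 0.1 for each, the smallest that 3 against 3 can give). Replicate 3 of WT without Al stood apart from its group, with 13966 genes at 1 FPKM or more. Its mean Spearman correlation with its own group was 0.918, the lowest of the 12 libraries.

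**Figure D2:**
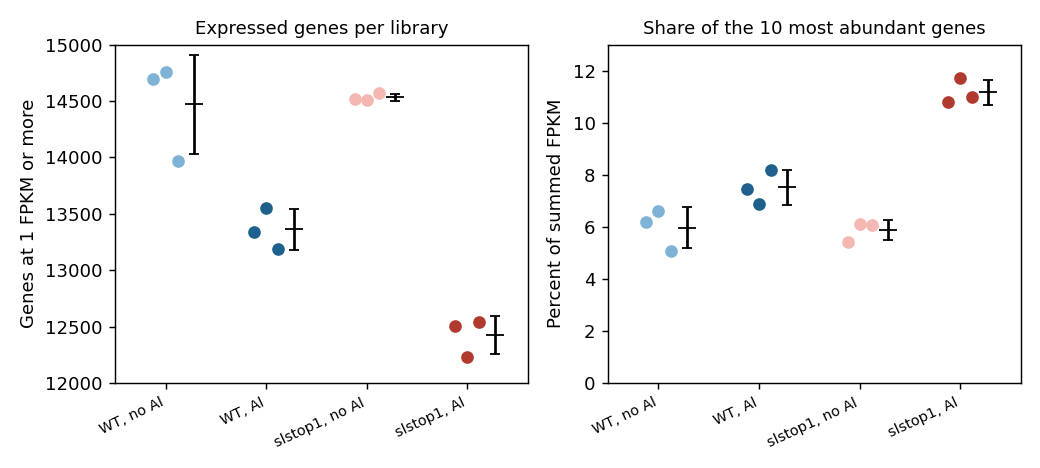
Number of genes at 1 FPKM or more (left; the axis does not start at 0) and percent of summed FPKM held by the 10 most abundant genes (right) in each library, with group mean and SD (n = 3). Both panels place the slstop1 libraries with Al apart from all others, at 12424 ± 171 genes and 11.2 ± 0.473%.

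The effect of Al on WT roots was broad. Of the tested genes, 9688 (60.9%) changed, 3478 upward and 6210 downward, and 2248 rises and 4149 falls were at least 1 on the log2 scale. A rise or fall of at least 4 on that scale was reached by 218 and 191 genes. Solyc03g120260.3 on chromosome 3 rose from 6.41 ± 1.60 to 4577 ± 1450 FPKM (SD, n = 3; log2 9.24 ± 0.253 SE, adjusted p = 4.9e-09). Solyc03g044850.1, also on chromosome 3, rose by 9.36 ± 0.551 on the log2 scale (adjusted p = 3.17e-07; 7.57 to 11.66 over the alternatives), from library values of 0, 0 and 4.7 FPKM to 1231 ± 417 FPKM. The largest fall belonged to Solyc00g072400.3 and Solyc10g076243.1, which have identical values in every library and are therefore uncertain as separate genes. Their WT libraries read 580, 680 and 238 FPKM without Al and 0.01, 2.92 and 0 FPKM with Al (log2 -8.17 ± 0.518, adjusted p = 4.61e-07; -10.47 to -6.30 over the alternatives). FER stood at 51.2 ± 7.97 FPKM without Al and 48.5 ± 18.3 FPKM with Al, which did not pass the test (adjusted p = 0.656).

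Falls outnumbered rises in WT on the FPKM scale, 64.1% of the calls, and this excess depended on the scaling. After median-of-ratios scaling 9659 genes were called, 4501 higher and 5158 lower (53.4% lower), and the median log2 change of all tested genes moved from -0.28 to -0.07. Quantile normalisation gave 4617 higher and 4909 lower; both scalings centre the changes by construction.

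In slstop1 the Al response reached more genes and was largely shared with WT. Al changed 10627 genes (66.8%), 3392 upward and 7235 downward, and 408 genes fell by at least 4 on the log2 scale, where 185 rose by as much. Solyc03g120260.3 rose here too, from 11.1 ± 2.60 to 8015 ± 180 FPKM (SD, n = 3; log2 9.40 ± 0.253, adjusted p = 3.46e-09). Solyc08g077330.3 on chromosome 8 rose from 1.5 ± 0.892 to 1080 ± 111 FPKM (log2 8.83 ± 0.385, adjusted p = 3.09e-08). On the same chromosome, Solyc08g078930.1 fell from 1520 ± 202 to 2.27 ± 1.65 FPKM (log2 -8.98 ± 0.687, adjusted p = 8.6e-07). The nearby Solyc08g078910.1, at 530, 515 and 522 FPKM without Al, was listed at 0 in all 3 slstop1 libraries with Al (adjusted p = 8.34e-07). FER fell from 30.9 ± 5.50 to 7.54 ± 0.394 FPKM (log2 -1.89 ± 0.267, adjusted p = 7.97e-05).

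The Al responses of the genotypes share no library. They had 2904 rises and 5931 falls in common, where independent lists would share 741.8 and 2825. Only 25 genes passed both tests in opposite directions, 20 that rose in WT and fell in slstop1 and 5 that did the reverse. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.933, and the slope of the major axis, slstop1 over WT, was 1.12. On the FPKM scale 68.1% of the calls in slstop1 were falls; with median-of-ratios scaling 5008 genes rose and 5678 fell (53.1% lower), and the median of all tested genes moved from -0.46 to -0.09. Quantile normalisation turned the excess, with 5478 higher and 5010 lower (47.8% lower).

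Without Al few genes passed the test between genotypes. Between slstop1 and WT 28 genes were called, 11 higher and 17 lower in slstop1, SlSTOP1 among the latter. Solyc07g009310.3 on chromosome 7 was at 110 ± 24.7 FPKM in slstop1 and 13.7 ± 4.28 FPKM in WT (SD, n = 3; log2 2.94 ± 0.343, adjusted p = 0.00809). Solyc06g017860.2 stood at 6.58 ± 0.559 FPKM in slstop1 and at 0.11, 1.13 and 0 FPKM in the WT libraries (log2 2.50 ± 0.289, adjusted p = 0.00809). Its log2 difference ran from 1.10 to 4.49 over the alternatives, and the call was lost in 2 of 21 (adjusted p from 0.000642 to 0.165). On chromosome 4, Solyc04g071580.3 was at 199 ± 48.5 FPKM in slstop1 and 1148 ± 343 FPKM in WT (log2 -2.50 ± 0.349, adjusted p = 0.0218). Solyc04g074540.2, at 5.41, 9.11 and 1.5 FPKM in WT, was listed at 0 in all slstop1 libraries (adjusted p = 0.0425); this call was lost in 16 of 21 alternatives (adjusted p from 0.00194 to 0.591). That of Solyc04g071580.3 was lost in 8 of 21 (0.00503 to 0.157). FER, at 51.2 ± 7.97 FPKM in WT and 30.9 ± 5.50 FPKM in slstop1, did not pass over all genes (adjusted p = 0.696). Its unadjusted limma p was 0.0218. Adjustment over a list of the 2 preset genes tested, SlSTOP1 being the other, left this p unchanged and adds no support.

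The number of genes called without Al, and its split, were unstable. The split turned to 9 higher and 3 lower without replicate 1 of WT without Al, 8 and 2 without its replicate 2, 9 and 7, 6 and 5, and 9 and 7 without replicate 1, 2 or 3 of slstop1 with Al, and was even at 15 and 15 with no filter on low values. The count was 10 when only these 6 libraries were fitted and lay between 7 and 48 when a single library was left out, the highest without replicate 3 of WT without Al.

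With Al the genotypes parted. There were 1469 genes called between slstop1 and WT, 178 higher and 1291 lower in slstop1. FER was among the lower, at 7.54 ± 0.394 FPKM in slstop1 against 48.5 ± 18.3 FPKM in WT (SD, n = 3; log2 -2.45 ± 0.267, adjusted p = 0.000524). Solyc03g097510.1 on chromosome 3, which rose with Al in WT to 152 ± 34.4 FPKM, was at 6.13 ± 2.68 FPKM in slstop1 with Al (log2 -4.47 ± 0.422, adjusted p = 0.00021). Solyc10g083410.1 stood at 0, 1.02 and 5.36 FPKM in slstop1 against 53.2 ± 11.7 FPKM in WT (log2 -4.51 ± 0.504, adjusted p = 0.000631). Higher in slstop1 were Solyc03g036460.2, at 35.6 ± 19.1 FPKM against 1.87 ± 3 FPKM (log2 4.05 ± 0.742, adjusted p = 0.0082), and again Solyc07g009310.3, at 41.9 ± 13.1 FPKM against 2.56 ± 1.46 FPKM (log2 3.62 ± 0.343, adjusted p = 0.00021). For Solyc03g036460.2 the difference without Al was of similar size but did not pass the test (log2 3.81 ± 0.742, adjusted p = 0.121), with 0, 1.35 and 0 FPKM in WT and 6.72, 28.5 and 27.4 FPKM in slstop1.

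The genotype difference with Al ran along the Al response. Of the 1291 genes lower in slstop1, 890 were genes that fell with Al in WT (504.1 for independent lists) and 177 were genes that rose (282.3). Of the 178 higher in slstop1, 100 rose with Al in WT (38.93) and 31 fell (69.51). These comparisons share the WT libraries with Al, which pushes errors that are independent between genes toward opposite directions. Of the genes called without Al, 8 were higher and 13 lower in slstop1 at both doses (0.123 and 1.38 for independent lists). In opposite directions, 1 was lower without Al and higher with Al (0.19), and 0 were the reverse (0.893).

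Genes higher in slstop1 with Al were not spread evenly over the genome. In a window of 20 neighbouring tested genes on chromosome 7, 9 were higher in slstop1, while the densest window of permuted placements held at most 6 (permutation p = 0.0001, the smallest that 10000 permutations give). Solyc07g009310.3 lies just beyond this window, which was chosen after the values were seen.

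**Figure D3:**
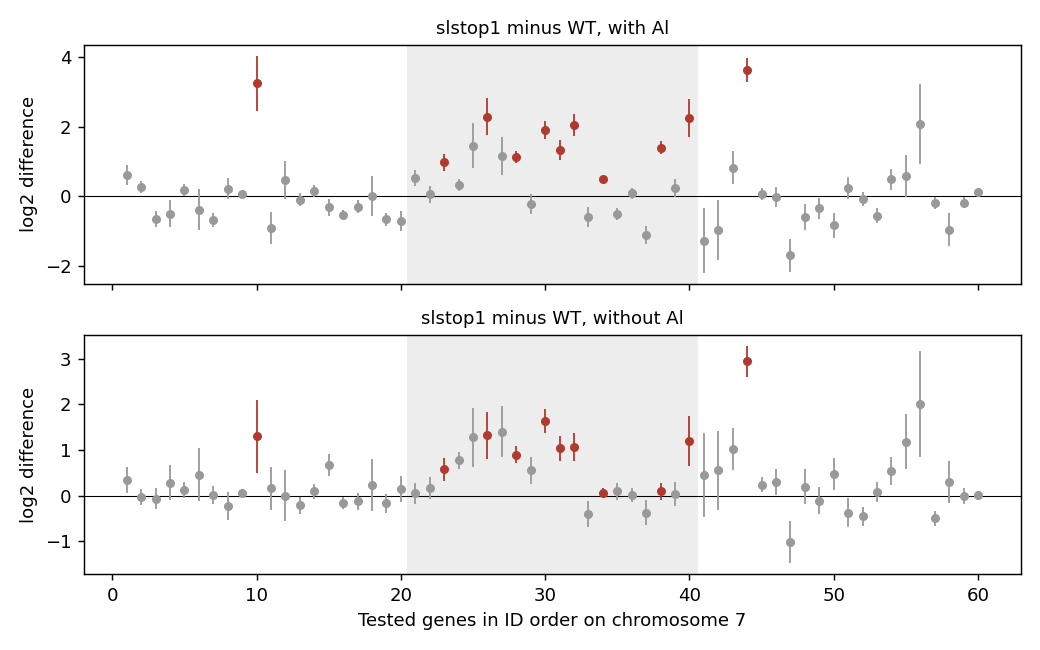
Log2 difference, slstop1 minus WT, with Al (top) and without Al (bottom) of tested genes in identifier order on chromosome 7; bars are SE, red marks genes higher in slstop1 with Al, and grey shading the densest window of 20 genes. All 9 red genes in the window are above 0 in both panels.

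The split of calls with Al moved from 87.9% lower to 63.1% lower with median-of-ratios scaling (477 higher and 814 lower). The count was 783 with quantile normalisation, 910 with only the 6 libraries compared, 788 without replicate 1 of WT with Al, 2401 without replicate 3 of WT without Al, and 862, 580 and 898 without replicate 1, 2 or 3 of slstop1 with Al.

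The interaction term asked directly whether the Al response differed between genotypes. It was called for 163 genes, 155 with a lower (more negative) response in slstop1 and 8 with a higher one. These calls are on the FPKM scale, on which the interaction of all tested genes had a median log2 of -0.185. Of the 155, 82 fell with Al in both genotypes, 36 fell in slstop1 and were not called in WT, and 37 rose in WT. Independent lists would share 33.9 genes that rose in WT and 60.53 that fell, but the interaction contains the WT libraries, so these are not the numbers that chance gives. Among those 37, 13 also rose in slstop1, 8 fell there, and the remainder were not called. Their median rise was 2.49 on the log2 scale in WT and 0.25 in slstop1, and their median genotype difference was 0.10 without Al and -1.78 with Al. Nearly the whole group, 152 of the 155, was also called lower in slstop1 with Al, a difference that is itself a term of the interaction and shares its libraries.

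Solyc10g083410.1 had the most negative interaction (log2 -5.01 ± 0.713, adjusted p = 0.0105; -6.46 to -3.53 over the alternatives): it was at 31.6 ± 4.85 FPKM without and 53.2 ± 11.7 FPKM with Al in WT, and at 44.9 ± 7.14 FPKM without Al in slstop1. This call was lost in 1 of 21 alternatives (adjusted p from 0.000693 to 0.0613). Next came Solyc04g010270.1 (log2 -3.75 ± 0.309, adjusted p = 0.000422), which fell from 63.1 ± 9.38 to 40.5 ± 7.46 FPKM in WT and from 61.8 ± 16.2 to 1.98 ± 0.468 FPKM in slstop1 (SD, n = 3). In the other direction, Solyc06g073890.3 was listed at 0 in WT with Al and at 3.47, 6.57 and 5.47 FPKM in slstop1 with Al (interaction adjusted p = 0.0413), a call lost in 13 of 20 alternatives (adjusted p from 0.00287 to 0.122). Without Al this gene read 5.31, 2.61 and 8.33 FPKM in WT and 5.14, 0 and 0.25 FPKM in slstop1, a difference (log2 -1.60, adjusted p = 0.677) that enters the interaction. Solyc03g123670.3 was at 4.84, 7.33 and 6.78 FPKM in slstop1 with Al, at 0.42, 0 and 0 FPKM in WT with Al, and listed at 0 without Al (adjusted p = 0.00116). For FER the interaction was -1.74 ± 0.378 and did not pass over all genes (limma adjusted p = 0.0575, range over alternatives 0.00345 to 0.178). It stayed uncalled in 18 of 21 alternatives. The lowest p came from leaving out replicate 2 of WT with Al, where FER was lowest (27.4 FPKM against 57.6 and 60.5). Adjusted over the list of the 2 preset genes tested, its limma p was 0.00156, which allows for only 2 genes, SlSTOP1 being the other. For SlSTOP1 the interaction was -0.61 ± 0.195 (adjusted p = 0.192). Its unadjusted limma p of 0.00971 was left unchanged by adjustment over the list alone.

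The count of interaction genes was 100 with median-of-ratios scaling, 84 of them lower in slstop1, and 63 with quantile normalisation, 47 of them lower. The scalings kept 92 and 54 of the 163 calls. The share of lower calls was 95.1% unscaled, 84% and 74.6%, and the median of all tested genes -0.185, -0.03 and 0.04. Part of the one-sided split thus depended on the scaling. Both scalings centre the changes by construction and cannot decide how much of it is real. The count of interaction genes ranged from 53 to 357 when a single library was left out, the highest without replicate 3 of WT without Al. In 10 of 12 groupings that kept the genotypes with Al and regrouped the libraries without Al, 163 genes or more were called.

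**Figure D4:**
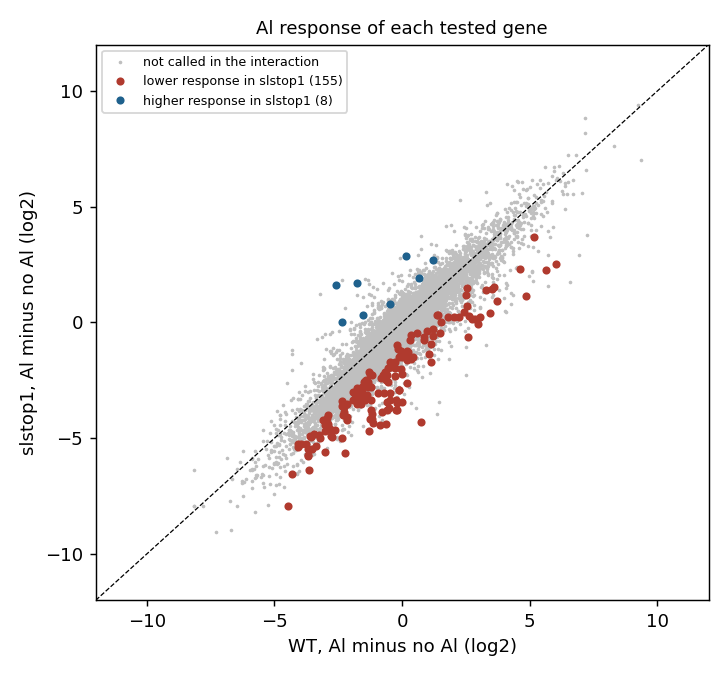
Log2 change with Al of each tested gene in WT (x axis) and slstop1 (y axis); the dashed line marks equal change. Red points are the 155 genes with a lower response in slstop1 by the interaction test and blue points the 8 with a higher one.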

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

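The tests of scaling, depth, shared libraries and gene order below were chosen after the patterns they bear on had been seen; the regroupings of libraries were fixed before. The Al response differed between genotypes, by the interaction test, for 163 genes. The named genes among them had interaction log2 values of -5.01 (Solyc10g083410.1), -3.75 (Solyc04g010270.1), 4.19 (Solyc06g073890.3, whose WT libraries with Al are listed at 0) and 2.69 (Solyc03g123670.3, listed at 0 without Al). The sizes of the last pair rest on groups at 0 and so on the pseudocount: they ran from 1.67 to 8.80 and from 1.13 to 5.19 over the alternatives. That of Solyc10g083410.1, with a library at 0, ran from -6.46 to -3.53. When genotypes were regrouped within each dose, 11 of 100 groupings, the real one included, gave 163 interaction genes or more, with 1427 as the highest of the others. By that share chance is not excluded, but the test decides little: all 10 of those other groupings were among the 12 that kept the genotypes together with Al, and so kept the genotype difference measured there, while the 87 groupings that mixed them with Al gave at most 6 genes. The count of 163 thus does not stand apart from other groupings of the libraries without Al. The grouping with 1427, several times the real count, points to a structure of the samples without Al, which was not tested. It exchanged replicate 3 of WT without Al, which stood apart from its group, for replicate 2 of slstop1 without Al. Swapping the genotypes of all libraries without Al gave 584 genes. In that grouping the genotype differences with and without Al are added rather than subtracted.

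Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. Refitted on its 6 libraries, the real split, 1 of 10 to reach its own count, called 8142 genes for Al in WT (highest of the others 3), 11453 for Al in slstop1 (1), 10 for slstop1 against WT without Al (6) and 910 with Al (2).

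On the FPKM scale more genes fell than rose with Al in both genotypes. A candidate explanation is that abundant genes took a larger share of a fixed total, which lowers all other values. With the 100 most abundant genes of any library left out of the total, falls still made up 59.1% of the calls in WT and 62.3% in slstop1 (median log2 -0.16 and -0.30), so these genes account for at most part of the excess and the explanation stays open for other abundant genes. Median-of-ratios scaling and quantile normalisation centre the changes by construction and cannot decide it. The depths argue against shallower libraries with Al as a cause, since the mean relative depth of the libraries with Al was 1.04 times that of the others. This ratio pools the genotypes. Within each genotype the relative depths with and without Al overlapped. In WT they were 0.982, 1.22 and 0.992 with Al and 1.13, 1.06 and 1.09 without. In slstop1 they were 1.0, 0.847 and 1.11 with Al and 0.939, 0.871 and 0.84 without. A real excess of falls stays open too.

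The genotype difference with Al followed the Al response, with r = 0.278 across genes against the WT response. Chance errors drawn for each gene on its own would give a negative r through the shared WT libraries. Simulations of this kind with the Al effect but no genotype effect reached at most -0.0916, and with no effect at all the median was -0.498. They hold no differences between whole libraries in the strength of the Al response, which could give r either sign. Chance of that kind is not excluded by them. The covariance was 0.244, against -0.0677 in the simulation with no effect at all. A shift of all genes by a larger share of abundant ones is argued against by the scaled values. After median-of-ratios scaling 497 of 814 lower genes fell and 350 of 477 higher genes rose in WT (264 and 135 for independent lists). A stronger Al response of the mutant, as a biological hypothesis, stays open, as does a difference in cell makeup of the roots, which was not tested.

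The genes higher in slstop1 with Al were dense in a window on chromosome 7 (permutation p = 0.0001, the smallest that 10000 permutations give). Adjacent copies that share reads may add to it. Counting each run of adjacent called genes once left 7, with the same p of 0.0001 and at most 5 in permuted placements. An uncalled gene ends a run, however, so copies with an uncalled gene between them were counted apart. Solyc07g009030.3 and Solyc07g009050.3, on either side of the called Solyc07g009040.3, were uncalled at log2 1.455 and 1.152 with Al. The count of runs therefore does not exclude such copies. A sequence difference linked to this region in the slstop1 line is a candidate explanation, for it should act at both doses. An effect of the slstop1 mutation itself, in a gene on chromosome 11, would also be present at both doses. The values without Al therefore cannot tell these explanations apart. In the libraries without Al, which are not shared with the comparison that defined the window, the mean log2 difference of its 20 genes was 0.57, and only 6 of 15567 windows, which overlap each other, had a higher mean. All 9 higher genes were above 0 without Al (median 1.03, against 1.39 with Al), although only 1 of them passed the test there. Another gene of the window was called lower in slstop1 with Al (log2 -1.11, adjusted p = 0.0288). Of the 168 other genes higher in slstop1 with Al and assigned to a chromosome, 120 were above 0 without Al (median 0.18).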

How the results depend on the processing

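Replicate numbers are shared across groups, and the labels do not say whether they mark shared batches. No positive pairing of same-numbered libraries was seen. Their residual correlations ran from -0.24 to 0.0925, 0 of 18 pairs exceeded 0.1, and 0 of 12 libraries correlated best with their own number. With 3 libraries per group this check is weak and does not exclude a shared batch. With the replicate block the counts were 8 genes between genotypes without Al (5 higher and 3 lower) and 69 for the interaction; the other counts stayed within 1.5 times of the unblocked ones. A log2 change of at least 1 left 6397 genes for Al in WT, 810 between genotypes with Al and 5771 genes shared by the Al responses, by its own construction. Requiring a mean of 5 FPKM left 16 genes between genotypes without Al. Only the 6 libraries compared gave 10 without and 910 with Al. Quantile normalisation gave 783 between genotypes with Al and 63 for the interaction, and median-of-ratios scaling 100 for the interaction. The cause of these last shifts was not tested. Leaving out a library gave 8717 to 9589 genes for Al in WT, 9682 to 11198 for Al in slstop1, 7 to 48 between genotypes without Al, 580 to 2401 with Al, and 53 to 357 for the interaction. Without Al the count was 12, 10 and 48 without WT replicate 1, 2 or 3 at no Al, 7, 11 and 10 without the slstop1 ones, and 16, 11 and 16 without the slstop1 ones with Al. For the interaction it was 79 and 357 without WT replicate 1 or 3 at no Al, 68 without WT replicate 1 with Al, 58, 53 and 53 without the slstop1 ones at no Al, and 77 and 71 without slstop1 replicate 1 or 2 with Al. With Al it was 2401 without WT replicate 3 at no Al, 788 without WT replicate 1 with Al, and 862, 580 and 898 without the slstop1 ones. With the 100 most abundant genes left out, an alternative added after seeing the data, all 5 counts stayed within 1.5 times. Among 641 values of named genes under alternatives, 0 reversed a called direction, 53 lost and 8 gained the call. The calls lost were those of Solyc04g074540.2 (16 alternatives), Solyc06g073890.3 (13), SlSTOP1 without Al (12), Solyc04g071580.3 (8), Solyc06g017860.2 (2), Solyc07g009310.3 without Al (1) and Solyc10g083410.1 in the interaction (1). The calls gained were those of the SlSTOP1 change in WT (3) and in slstop1 (2) and of the FER interaction (3; adjusted p 0.00345 without WT replicate 2 with Al, 0.0478 with a pseudocount of 0.1 and 0.0438 with a mean of 5 FPKM). Gene list tests, and their alternatives, were not run, because the lists were not matched. Depth limits are unknown without read totals.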

Other observations

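The 37 genes that rose with Al in WT and had a lower response in slstop1 had a median genotype difference of -1.78 with Al. Genes picked on extreme WT values may regress toward the mean, which was tested by holding out a library of each genotype with Al, in all 9 choices, and picking genes on the remaining 10. The median genotype difference between the held-out libraries ran from -3.19 to -1.09, over 4 to 54 genes, so regression alone does not account for it. This test was set before its result was seen. FER was not in that group, as neither its change with Al in WT nor its interaction passed over all genes (limma adjusted p = 0.656 and 0.0575).

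Genes that rose with Al in WT sat next to each other more often than permuted placements gave, a test chosen after the pattern was seen. There were 922 adjacent pairs of tested genes that both rose, against a median of 758 and a maximum of 840 in 10000 permutations (p = 0.0001, the smallest they can give). Tandem copies and shared reads were not separated from joint regulation here. A nearby pair on chromosome 8, Solyc08g078910.1 and Solyc08g078930.1, fell together in both genotypes; in WT with Al they were at 1.67, 16.6 and 0.44 FPKM and at 13.6, 74.7 and 5.76 FPKM.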
